A study of Mus musculus with 10 samples.

How the data were processed

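The study sequenced RNA of cells sorted from mouse brains with glioma. Per the labels, total RNA was extracted with a NucleoSpin kit, amplified to cDNA from random and poly(dT) primers with a NuGEN Ovation kit, made into libraries with a TruSeq DNA kit and read on an Illumina HiSeq instrument. Per the labels, the authors made reads with bcl2fastq 1.8.3, aligned them to mm10 with TopHat and computed FPKM per transcript with Cufflinks, with no version given for either tool. Per the file headers, each deposited file gives for 63241 transcripts the FPKM, its interval, a status and a coverage value, which Cufflinks computed from the aligned reads before deposit. The coverage column served only to compare the depth of the libraries. The strand of the reads is not stated, so overlapping and antisense genes cannot be separated.

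The deposited transcripts carry no gene names. Each was matched by coordinates to the GENCODE M21 annotation, by shared ends, spliced length or an overlap of spans of at least 0.5 (intersection over union) with a lead of 0.1 over the next gene. In all 83.2% of transcripts were matched. Of 6931 transcripts held out of the match, 67.5% were given a gene and 99.0% of these the right one. FPKM values were summed per gene. The 7489 transcripts on loci under 200 bp were left out, as were 11 genes with a status other than OK in a library. Genes with a mean of at least 1 FPKM over the 10 libraries were kept.

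Values were taken as log2(FPKM + 1) and fitted with limma (version 3.58.1, R 4.3.3) over all 10 libraries in 5 groups of 2, with an eBayes trend, 5 residual degrees of freedom and a median of 5.6 prior degrees of freedom. The tests were two-sided. Adjusted p values are Benjamini-Hochberg values from limma over the genes of a comparison, and a gene was called below 0.05. The deposited values were not rescaled, and upper-quartile scaling, quantile normalization and a scaling to equal totals served as alternatives. Between groups of 2 libraries an exact permutation test of 1 gene could not pass 0.05, and all p come from the pooled fit. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists of a comparison.

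The 25 lists with at least 5 tested members were astrocyte, oligodendrocyte precursor, myelinating oligodendrocyte, neuron, microglia, monocyte and macrophage, general leukocyte and myeloid, lymphocyte, endothelial, fibroblast, neural stem cell, synapse, secreted synaptogenic factor, glutamate and GABA handling, DNA replication, mitosis, mesenchymal glioma, extracellular matrix and invasion, hypoxia, interferon response, antigen presentation, immediate early, p53 target, MAPK output and ribosomal protein. Neutrophil, mural cell, erythroid, ependymal, edited gene and sort marker lists were given as values. Some genes are members of several lists. The lists, the groups, the model, the rule for named genes and the alternatives other than those said to be added were fixed before the data were examined.

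The rule for named genes took, among genes called whose libraries did not overlap between groups, the 8 with the largest log2 difference in each direction for comparisons among P1, P2 and P5, and 5 in each direction for those with Bulk or Neg. Clone and predicted names, antigen receptor segments and small RNA genes were left out. Up to 4 members of each list with the smallest p were added, with the edited genes and sort markers.

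The fit was tested on simulated data over 10541 genes and 5 runs, with the spread of each gene in the fit of all 10 libraries. In each run 200 genes with a mean log2(FPKM + 1) above 2 were changed in P1, so recovery among lower genes was not tested. In P1 against P2 the fit recovered 28.2% of changes of log2 1 and 95.6% of changes of log2 2, with 7.2% false among its calls. In P2 against P5, where no change was put in, it called 0 genes. Of lists drawn at random, 4.1% had a camera p under 0.05 in P1 against P5, at the preset correlation. The simulated genes varied independently, so this does not test lists of genes that move together. Further steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.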

Results

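Gene expression was measured by RNA sequencing in 10 libraries of cells sorted from the brains of mice with glioma. The tumours were started by in utero electroporation of guide RNA vectors against NFI, PTEN and p53 together with Cas9 and a GFP reporter. The libraries fell into 5 groups of 2 replicates, named P1, P2, P5, Bulk and Neg in the sample titles. The series text speaks of 3 glioma cell populations, taken here to be P1, P2 and P5. The labels give neither the surface markers of each gate nor what Bulk and Neg were sorted on, nor whether replicates came from separate animals, so each p measures only the spread between these samples. Values are the mean deposited FPKM ± SD of the 2 libraries of a group, with the group named first given first. Log2 differences, some with their standard error (SE), are on the log2(FPKM + 1) scale, which understates the change of low genes. Each gene given with a log2 difference passed the limma test of that comparison. Counts of list genes at an unadjusted p take both directions together. Depth in fragments is unknown. The total FPKM of a library was 262677 and 256816 in P1 and between 161898 and 196859 in the other groups. The relative depth read from the coverage column ran from 0.59 in P1 replicate 1 to 1 in P5 replicate 4. Each library listed 63241 transcripts, and 10541 genes were tested. Coordinates are 1-based on the mm10 build. At least 10% of the 50-base words of Apoc2, Itgam, Hsd3b7, Hba-a1, Hbb-bs, Hspb1, Egfl8, H2-DMb1, H2-T-ps, H2-T23, Ly6c2, Glul, Taf1d, Csf3r and Rpl30 occur in other genes, so their values are uncertain.

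The edited genes were detected in each library. Pten, the phosphatase that opposes PI3-kinase signalling, lay between 6.40 and 13.5 FPKM, and Trp53, which encodes p53, between 15.2 and 35.6 FPKM. Trp53 was higher in P1 than in P2 (34.7 ± 1.34 against 20.7 ± 2.55 FPKM, log2 0.72, SE 0.22, adjusted p = 0.0477). That call lay close to the threshold, on FPKM that were not rescaled, and the median of all genes was itself 0.26 higher in P1. Nf1 lay between 3.63 and 14.1 FPKM. The label NFI can also stand for the nuclear factor I family. Nfia, one of its members and a regulator of glial fate, lay between 2.93 and 18.4 FPKM, and Nfib was higher in P1 than in P2 (13.2 ± 0.696 against 1.45 ± 0.579 FPKM, log2 2.55, SE 0.28, adjusted p = 0.000231). FPKM summed over a locus need not fall after small deletions, so these levels check neither the editing nor the labels. The sort was directed against stem and endothelial cells. Prom1, a marker of glioma stem cells, stayed between 0.083 and 1.66 FPKM, below the level needed for testing. Pecam1, an endothelial adhesion molecule, was lower in P2 than in P5 (0.458 ± 0.00757 against 2.95 ± 0.0107 FPKM, log2 -1.44, SE 0.28, adjusted p = 0.0156). Itgav, Cd63 and Tfrc, surface molecules used to sort astrocytes, did not pass the test between any 2 of P1, P2 and P5, with the smallest adjusted p at 0.159 for Cd63 in P1 against P2.

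Beside the mitochondrial gene mt-Co1, genes of myeloid cells and of antigen presentation held the highest values in every group. Cd74, the chaperone of MHC class II, reached 12320.0 ± 2368 FPKM in P1, 7556 ± 639.9 in P2, 4536 ± 454 in P5, 8809 ± 272 in Bulk and 6692 ± 1123 in Neg. Ctss, a lysosomal protease of microglia and macrophages, lay at 4690.0 ± 30.96 FPKM in P1 and 2104 ± 191 FPKM in Neg. Mbp, the major myelin basic protein, stood at 2825 ± 93.6 FPKM in Bulk, 2599 ± 291 in P1, 1000.0 ± 242 in P5, 310.1 ± 33.9 in Neg and 120.3 ± 35.9 in P2. The correlation of replicates across genes was 0.906 to 0.955, against at most 0.901 between libraries of different groups (genes are not independent replicates). The first principal component held 40% of the variance, with Neg at one end and P1 at the other, and the second held 13.9%. Of the short lists, the neutrophil genes S100a8 and S100a9 stayed at or below 12.6 FPKM in all libraries, Camp was listed at 0 in all 10, and Csf3r lay between 31.5 and 69.2 FPKM. The mural cell gene Rgs5 lay between 0.211 and 8.37 FPKM, and Anpep between 2.82 and 20.9 FPKM. The ependymal gene Foxj1 was listed at 0 in all 10 libraries, and Rsph1 reached 3.50 FPKM in P1 replicate 1. The erythroid gene Alas2, for haem synthesis, was at 2.61 and 5.59 FPKM in Neg and at most 1.92 FPKM elsewhere. A test for any difference among P1, P2 and P5 called 2014 genes. Without 1 library this count was 899 (P2 replicate 4), 1046 (P2 replicate 3), 1259 (P1 replicate 4) or 1298 (P1 replicate 1).

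**Figure D1:**
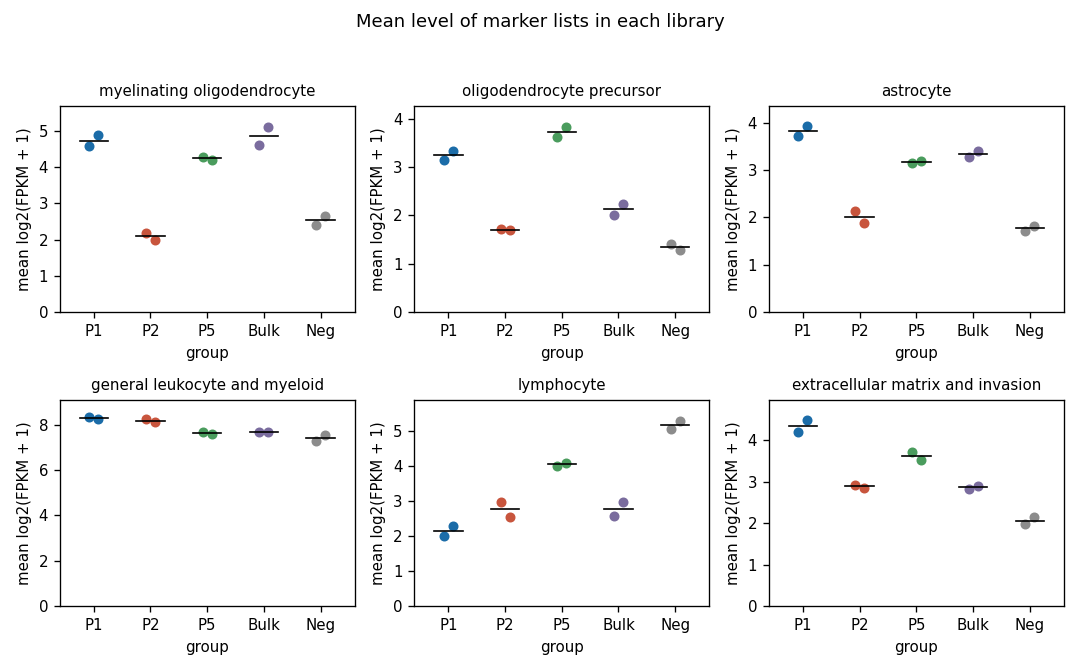
Mean log2(FPKM + 1) of 6 gene lists in each of the 10 libraries, by group. Points are libraries and bars the mean of the 2 libraries; myelin genes lay at 2 and 2.19 in the P2 libraries and at 4.57 and 4.87 in the P1 libraries, while lymphocyte genes lay highest in Neg, at 5.05 and 5.27.

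P1 carried far more transcripts of the oligodendrocyte lineage and of astrocytes than P2, and far fewer immediate early transcripts. With an estimated correlation the immediate early list alone kept its call (adjusted p = 0.0215), while those of myelin, astrocytes and precursors lost theirs (0.0675, 0.0633 and 0.0633). Mbp was at 2599 ± 291 against 120.3 ± 35.9 FPKM, log2 4.45. Plp1, the main protein of central myelin, was at 324 ± 82.1 against 17.99 ± 4.05 FPKM, log2 4.09. Mobp, another myelin protein, was at 284 ± 51.3 against 11.9 ± 4.02 FPKM, log2 4.49. Atf3, a stress-induced transcription factor, was at 33.1 ± 4.35 against 236 ± 3.61 FPKM, log2 -2.80. Zfp36, which promotes decay of inflammatory mRNAs, was at 186 ± 11.7 against 976 ± 7.44 FPKM, log2 -2.39. Dusp1, a phosphatase of MAP kinases, was at 88.4 ± 4.68 against 469 ± 31.4 FPKM, log2 -2.39. Of 10 leukocyte genes 1 was called, and the list did not pass (median log2 0.17, camera adjusted p = 0.961), its median turning to -0.16 with upper-quartile scaling, -0.27 after quantile normalization and -0.26 with equal totals. Of 12 microglia genes limma called 0, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. That list did not pass (median log2 -0.10, camera adjusted p = 0.0946; fry adjusted p = 0.505).

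Of 13 myelinating oligodendrocyte genes 12 were higher in P1 (median log2 2.62, 12 adjusted over the list alone, camera adjusted p = 9.62e-11, adjusted p = 0.0675 with an estimated correlation). Of 13 astrocyte genes 11 were higher (median log2 1.64, 11 adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.0633 with an estimated correlation). Among them were S100b, a glial calcium-binding protein (77.3 ± 16.3 against 5.25 ± 0.637 FPKM, log2 3.64), and Slc1a2, the main astrocyte glutamate transporter (19.7 ± 1.13 against 2.28 ± 0.549 FPKM, log2 2.67). Of 12 oligodendrocyte precursor genes 8 were higher (median log2 1.46, 10 adjusted over the list alone, camera adjusted p = 1.18e-05, adjusted p = 0.0633 with an estimated correlation). Among them were the lineage transcription factors Sox10 (42.3 ± 6.88 against 5.31 ± 1.301 FPKM, log2 2.79) and Olig1 (39.1 ± 6.24 against 7.53 ± 3.24 FPKM, log2 2.28). The list of glutamate and GABA handling, which holds astrocyte genes such as Slc1a2 as well as receptors, had 7 of 11 genes higher (median log2 1.27, 8 adjusted over the list alone, camera adjusted p = 0.000111, adjusted p = 0.0671 with an estimated correlation). Among them was the metabotropic receptor Grm5 (7.15 ± 0.944 against 0.334 ± 0.04897 FPKM, log2 2.61).

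Of 17 genes of extracellular matrix and invasion 12 were higher in P1 (median log2 1.42, 13 adjusted over the list alone, camera adjusted p = 1.62e-06, adjusted p = 0.0671 with an estimated correlation). Among them were the collagens Col1a1 (log2 2.99, SE 0.28) and Col4a1 (log2 2.33, SE 0.27). Sparc, a secreted matrix glycoprotein, was at 742 ± 2.87 against 170.0 ± 25.1 FPKM, log2 2.13. Of the 8 secreted synaptogenic factors 4 were higher (median log2 1.43, 4 adjusted over the list alone, camera adjusted p = 0.0404, adjusted p = 0.262 with an estimated correlation). Of 5 fibroblast genes 3, all collagens of the matrix list, were higher (median log2 1.81, 3 adjusted over the list alone, camera adjusted p = 0.00489, adjusted p = 0.0758 with an estimated correlation). Of 12 genes of MAPK output 5 were higher (median log2 0.88, 7 adjusted over the list alone, camera adjusted p = 0.0404, adjusted p = 0.164 with an estimated correlation). Among them were the feedback inhibitor Spry2 (log2 2.10, SE 0.29) and cyclin D1, Ccnd1 (log2 1.83, SE 0.30). Mitosis genes were higher for 4 of 17 (median log2 0.55, 4 adjusted over the list alone, camera adjusted p = 0.0477, adjusted p = 0.262 with an estimated correlation). The ubiquitin-conjugating enzyme Ube2c (log2 1.88, SE 0.35) and topoisomerase Top2a (log2 0.89, SE 0.25) were among them. Of 14 DNA replication genes 1, Rrm2 (log2 1.45, SE 0.39), was higher (median log2 0.50, camera adjusted p = 0.622). Of 10 neural stem cell genes 4 were higher (median log2 0.85, 4 adjusted over the list alone, camera adjusted p = 0.0429, adjusted p = 0.262 with an estimated correlation). Among them were the radial glial lipid carrier Fabp7 (log2 2.88, SE 0.40) and the intermediate filament Nes (log2 2.31, SE 0.34). Of 61 ribosomal protein genes 12 were higher and 2 lower (median log2 0.53, 16 adjusted over the list alone, camera adjusted p = 0.00519, adjusted p = 0.5 with an estimated correlation). Of these 61 genes 53 lie in the shortest of 5 equal classes of genes by transcript length, whose median in P1 against P2 was 0.42, against 0.2 to 0.26 in the other classes. The mitochondrial chromosome held 7.89% and 6.57% of the FPKM in P1 and 3.08% to 5.23% in the other libraries.

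Of the 14 immediate early genes 13 were lower in P1 (median log2 -1.75, 14 adjusted over the list alone, camera adjusted p = 1.05e-22, adjusted p = 0.0215 with an estimated correlation). Among them was the transcription factor Fos (28.8 ± 5.37 against 129 ± 12.04 FPKM, log2 -2.13). Monocyte and macrophage genes were lower for 4 of 9 (median log2 -0.29, 4 adjusted over the list alone, camera adjusted p = 0.000345, adjusted p = 0.0633 with an estimated correlation). Among them were Ly6c2 (4.24 ± 1.07 against 17.97 ± 3.81 FPKM, log2 -1.86) and the monocyte chemokine receptor Ccr2 (0.955 ± 0.404 against 6.27 ± 1.81 FPKM, log2 -1.89). Lymphocyte genes were lower for 2 of 11 (median log2 -0.55, 3 adjusted over the list alone, camera adjusted p = 9.4e-05, adjusted p = 0.143 with an estimated correlation). These were granzyme B (Gzmb, 1.501 ± 0.497 against 8.12 ± 1.19 FPKM, log2 -1.87) and the T cell receptor subunit Cd3g (5.805 ± 0.571 against 13.2 ± 4.04 FPKM, log2 -1.03). The lists of neurons, synapses, endothelial cells, mesenchymal glioma, hypoxia, interferon response, antigen presentation and p53 targets did not pass, with camera adjusted p from 0.0514 for synapses to 0.605 for hypoxia and antigen presentation. In 3 of these the test, made against all other genes, gave a lower direction although the median was above 0: mesenchymal glioma (0.08), hypoxia (0.13) and interferon response (0.01).

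In the whole comparison 1888 genes passed, 1495 higher and 393 lower in P1. The largest differences by the rule for named genes included Cryab, a small heat shock protein (229 ± 22.1 against 15.9 ± 8.68 FPKM, log2 3.86), and Plekhb1 (151 ± 3.67 against 10.3 ± 1.68 FPKM, log2 3.76) on the higher side. On the lower side was Klf2, a transcription factor of quiescent immune and endothelial cells (13.3 ± 3.57 against 105 ± 6.64 FPKM, log2 -2.91; chromosome 8, 72319033 to 72321656). Rgs1, a regulator of G protein signalling, was at 48.4 ± 5.81 against 342 ± 22.1 FPKM, log2 -2.80. The chemokine-binding receptor Ccrl2 was at 14.2 ± 3.91 against 97.8 ± 1.93 FPKM, log2 -2.72. The stress cytokine Gdf15 was at 0.866 ± 0.492 against 10.9 ± 0.942 FPKM, log2 -2.70. Nfkbid, a nuclear inhibitor of NF-kappa-B, was at 4.04 ± 2.33 against 29.8 ± 4.602 FPKM, log2 -2.68. Rarres2, which encodes chemerin, was at 19.6 and 30.9 FPKM in P1 and listed at 0 in both P2 libraries. Ten1 was at 16.4 and 20.4 FPKM and Commd1 at 16.8 and 16.9 FPKM in P1, both listed at 0 in P2. Zeros of these genes differed between replicates elsewhere: Ten1 was listed at 0 and at 10.55 FPKM in Neg, and Commd1 at 0 and at 12.7 FPKM in Bulk. Strada was at 5.24 and 6.55 FPKM and Srrd at 3.88 and 8.18 FPKM in P2, both listed at 0 in P1. The median of all genes was 0.26 higher in P1 on the log2 scale, and without that shift the split came to 807 higher and 677 lower with upper-quartile scaling, 680 and 645 after quantile normalization, and 600 and 842 with each library scaled to the same total. Without 1 library the count was 672 (P2 replicate 4), 851 (P2 replicate 3), 1030 (P1 replicate 4) or 1204 (P1 replicate 1).

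**Figure D2:**
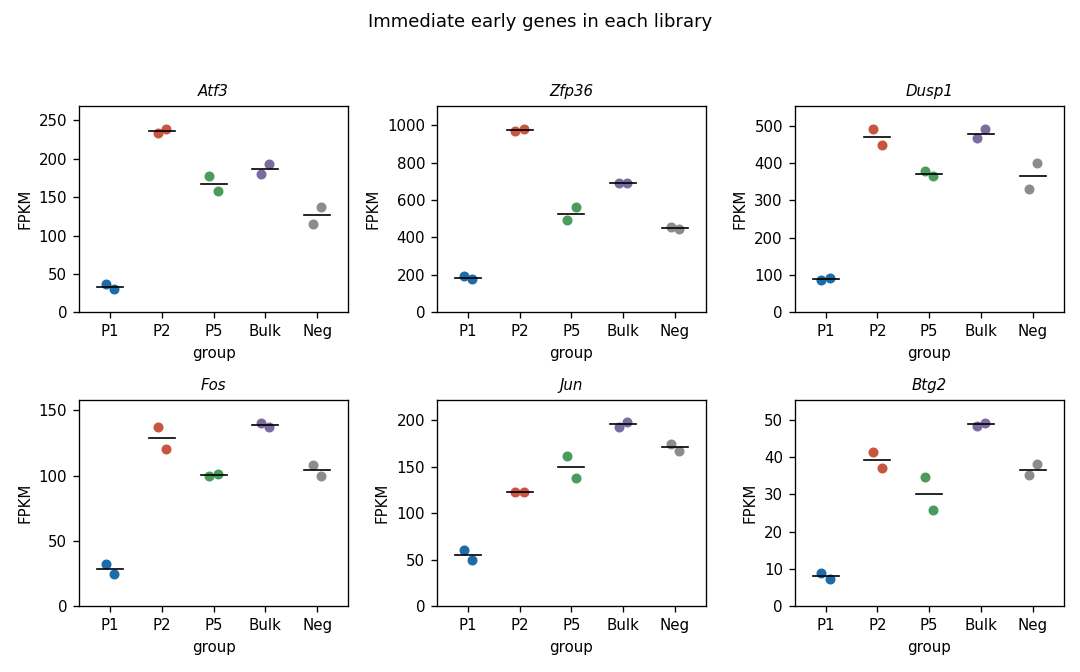
FPKM of 6 immediate early genes in each of the 10 libraries, by group. Points are libraries and bars the mean of the 2 libraries; Atf3 lay at 30.1 and 36.2 FPKM in the P1 libraries and between 115 and 238 FPKM in the other 8.

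P1 was lower than P5 in immediate early genes, the only list here to keep its call with an estimated correlation. The calls of the lymphocyte list, lower in P1, and of the matrix and leukocyte lists, higher in P1, were lost there (adjusted p = 0.0814, 0.184 and 0.199). In P1, lymphocyte genes were lower for 9 of 11 (median log2 -1.95, 10 adjusted over the list alone, camera adjusted p = 1.24e-12, adjusted p = 0.0814 with an estimated correlation). The T cell receptor subunit Cd3e was at 28.97 ± 2.97 against 131 ± 6.58 FPKM, log2 -2.15. The cytotoxic granule protein Nkg7 was at 17.4 ± 3.46 against 103 ± 20.4 FPKM, log2 -2.50 and Gzmb at 1.501 ± 0.497 against 26.4 ± 1.805 FPKM, log2 -3.47. Of 14 immediate early genes 11 were lower in P1 (median log2 -1.63, 13 adjusted over the list alone, camera adjusted p = 2.81e-19, adjusted p = 0.0315 with an estimated correlation). Atf3 was at 33.1 ± 4.35 against 168 ± 14.4 FPKM, log2 -2.31 and Dusp1 at 88.4 ± 4.68 against 371 ± 9.06 FPKM, log2 -2.06. Leukocyte genes were higher in P1 for 6 of 10 (median log2 0.84, 7 adjusted over the list alone, camera adjusted p = 0.0002, adjusted p = 0.199 with an estimated correlation). Fcer1g, the signalling chain of Fc receptors, was at 1279 ± 264 against 462 ± 52.1 FPKM, log2 1.46. Microglia genes were higher for 3 of 12 (median log2 0.64, 6 adjusted over the list alone, camera adjusted p = 0.00276, adjusted p = 0.199 with an estimated correlation). The fractalkine receptor Cx3cr1 was at 126 ± 3.15 against 56.5 ± 5.09 FPKM, log2 1.14.

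Of 17 matrix genes 7 were higher in P1 (median log2 1.01, 9 adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.184 with an estimated correlation). Among them were the membrane protease Mmp14 (68.6 ± 0.855 against 25.9 ± 3.38 FPKM, log2 1.38) and fibronectin, Fn1 (56.6 ± 15.5 against 21.7 ± 2.86 FPKM, log2 1.32). Secreted synaptogenic factors were higher for 2 of 8 (median log2 0.52, 3 adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.387 with an estimated correlation). These were Sparc (log2 1.74, SE 0.17) and Thbs2 (log2 1.52, SE 0.32). Fibroblast genes, again the collagens, were higher for 3 of 5 (median log2 1.26, 3 adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.184 with an estimated correlation). Astrocyte genes were higher for 3 of 13 (median log2 0.69, 4 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.184 with an estimated correlation). These were Ndrg2 (log2 1.48, SE 0.31), Slc1a2 (log2 1.06, SE 0.25) and the glutamine synthetase Glul (log2 0.69, SE 0.17). The oligodendrocyte precursor list was lower in P1 as a group (median log2 -0.73, 0 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.184 with an estimated correlation). Of its 12 genes limma called 0 over all genes, with 7 at an unadjusted p under 0.05 and a fry adjusted p = 0.0186. The 7 were counted in either direction. Sox10, among the smallest p of the list, was higher in P1 (42.3 ± 6.88 against 23.8 ± 0.311 FPKM), while Olig2, Gpr17 and Ascl1 were lower. Of 13 myelin genes 3 were higher, and the list did not pass (median log2 0.35, camera adjusted p = 0.0777; median -0.18 with equal totals). Mbp was at 2599 ± 291 against 1000.0 ± 242 FPKM, log2 1.39. Of 12 antigen presentation genes 5 were higher (median log2 0.49, 5 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.331 with an estimated correlation). Among them was Cd74 (log2 1.43, SE 0.19), but the median of this list turned to -0.12 after quantile normalization and to -0.04 with equal totals. Of 12 p53 targets 4 were lower (median log2 -0.21, 6 adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.184 with an estimated correlation). Among them were the pro-apoptotic genes Pmaip1 (log2 -2.09, SE 0.39) and Bbc3 (log2 -1.47, SE 0.37) and the p53 ubiquitin ligase Mdm2 (log2 -0.85, SE 0.22). Of 61 ribosomal protein genes 8 were higher and 2 lower (median log2 0.44, 18 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.562 with an estimated correlation). The shortest class of genes had a median of 0.25 here, against 0.06 to 0.1 in the others, and P1 had the higher mitochondrial share. The lists of monocytes (0.27), neural stem cells (0.23), synapses (0.22) and mesenchymal glioma (0.27) did not pass, and the test gave a lower direction although their medians were above 0.

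By the rule for named genes the largest differences on the lower side were the mast cell proteases Mcpt1 (2.33 ± 0.345 against 65.3 ± 16.1 FPKM, log2 -4.30; chromosome 14, 56017971 to 56020384) and Mcpt2 (1.797 ± 2.12 against 43.01 ± 14.03 FPKM, log2 -4.18). The lymphocyte homing receptor Ccr7 was at 1.15 ± 0.349 against 19 ± 1.21 FPKM, log2 -3.22. Gstp3 was at 0.691 ± 0.618 against 15.8 ± 13.7 FPKM, log2 -3.07. Traf1, an adaptor of TNF receptors, was at 1.72 ± 1.298 against 18.8 ± 6.18 FPKM, log2 -2.91. Taf1d and Plppr3 were listed at 0 in both P1 libraries and stood at 15.4 and 5.696 FPKM and at 9.98 and 10.6 FPKM in P5. In P2, Plppr3 stood at 7.68 FPKM in replicate 3 and was listed at 0 in replicate 4. On the higher side was Npy, neuropeptide Y (18.9 ± 1.02 against 1.76 ± 2.03 FPKM, log2 3.08). Daam2, a formin, stood at 18.1 and 13.3 FPKM in P1, and in P5 it was listed at 0 and at 1.94 FPKM. The transcription factor Atf5 stood at 17.9 and 24.2 FPKM in P1, against 6.22 FPKM and a value listed at 0. Rnf214 stood at 12.6 and 10.98 FPKM, against 2.996 FPKM and a value listed at 0. Slirp (47.4 and 83.3 FPKM in P1), Commd1, Arsg (4.41 and 9.86 FPKM) and Mia3 (5.803 and 6.42 FPKM) were listed at 0 in both P5 libraries. Replicates of other groups disagreed on Slirp (0 and 58.4 FPKM in P2), Commd1 (0 and 12.7 FPKM in Bulk) and Mia3 (6.996 FPKM and 0 in Neg). In all 940 genes passed, 548 higher and 392 lower in P1. The median of all genes was 0.11 higher, and the split was 313 higher and 453 lower with upper-quartile scaling, 189 and 391 after quantile normalization, and 82 and 978 with equal totals. With 1 library left out the count was 324 (P5 replicate 4), 338 (P1 replicate 1), 343 (P5 replicate 1) or 460 (P1 replicate 4).

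P2 held fewer glial transcripts than P5 and more of those of microglia. The lymphocyte list, lower in P2, and the leukocyte list, higher in P2, lost their calls with an estimated correlation (both adjusted p = 0.0717), and the monocyte list kept its call without a gene called over all genes. All 12 oligodendrocyte precursor genes were lower in P2 (median log2 -2, 12 adjusted over the list alone, camera adjusted p = 4.48e-13, adjusted p = 0.027 with an estimated correlation). Among them were Olig2 (2.71 ± 0.108 against 22.2 ± 1.88 FPKM, log2 -2.64), the precursor receptor Gpr17 (1.74 ± 0.996 against 14.3 ± 1.94 FPKM, log2 -2.53) and the proteoglycan Vcan (4.504 ± 0.6603 against 21.04 ± 1.11 FPKM, log2 -2.01). Of 13 myelin genes 11 were lower (median log2 -2.14, 11 adjusted over the list alone, camera adjusted p = 3.65e-14, adjusted p = 0.0436 with an estimated correlation). Mbp was at 120.3 ± 35.9 against 1000.0 ± 242 FPKM, log2 -3.06 and Plp1 at 17.99 ± 4.05 against 178 ± 71.3 FPKM, log2 -3.19. Of 13 astrocyte genes 6 were lower (median log2 -0.98, 9 adjusted over the list alone, camera adjusted p = 7.91e-06, adjusted p = 0.0436 with an estimated correlation). S100b was at 5.25 ± 0.637 against 54.7 ± 17.4 FPKM, log2 -3.12. Of 11 lymphocyte genes 5 were lower (median log2 -1.27, 9 adjusted over the list alone, camera adjusted p = 5.62e-07, adjusted p = 0.0717 with an estimated correlation). Cd3e was at 43.2 ± 8.55 against 131 ± 6.58 FPKM, log2 -1.60.

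Microglia genes were higher in P2 for 4 of 12 (median log2 0.64, 5 adjusted over the list alone, camera adjusted p = 8.16e-09, adjusted p = 0.0436 with an estimated correlation). Cx3cr1 was at 119 ± 4.65 against 56.5 ± 5.09 FPKM, log2 1.06 and the colony-stimulating factor receptor Csf1r at 292 ± 19.3 against 151 ± 11.1 FPKM, log2 0.94. Leukocyte genes were higher for 5 of 10 (median log2 0.64, 5 adjusted over the list alone, camera adjusted p = 1.59e-08, adjusted p = 0.0717 with an estimated correlation). Ctss was at 4445 ± 10.4 against 2631 ± 258 FPKM, log2 0.76. The monocyte list was higher as a group (median log2 0.57, 1 adjusted over the list alone, camera adjusted p = 9.96e-05, adjusted p = 0.0436 with an estimated correlation). Of its 9 genes limma called 0 over all genes, with 3 at an unadjusted p under 0.05 and a fry adjusted p = 0.000591. Glutamate and GABA handling was lower for 5 of 11 genes (median log2 -1.37, 10 adjusted over the list alone, camera adjusted p = 5.62e-07, adjusted p = 0.0436 with an estimated correlation). Among them was the AMPA receptor subunit Gria2 (0.8304 ± 0.251 against 7.67 ± 1.01 FPKM, log2 -2.25). Synapse genes were lower for 4 of 14 (median log2 -0.75, 6 adjusted over the list alone, camera adjusted p = 0.0161, adjusted p = 0.0914 with an estimated correlation). The presynaptic adhesion molecule Nrxn1 (log2 -2.12, SE 0.30) was among them. Neuron genes were lower for 3 of 5 (median log2 -1.36, 3 adjusted over the list alone, camera adjusted p = 0.00452, adjusted p = 0.0717 with an estimated correlation). These were Map2 (log2 -1.36, SE 0.29), Snap25 (log2 -1.50, SE 0.33) and Dcx (log2 -1.53, SE 0.37). Neural stem cell genes were lower for 4 of 10 (median log2 -1.30, 6 adjusted over the list alone, camera adjusted p = 0.00678, adjusted p = 0.154 with an estimated correlation). Among them were Fabp7 (log2 -2.38, SE 0.40) and the proneural factor Ascl1 (log2 -2.05, SE 0.47). Matrix genes were lower for 6 of 17 and higher for 2 (median log2 -0.76, 12 adjusted over the list alone, camera adjusted p = 0.00809, adjusted p = 0.154 with an estimated correlation). The lower ones included the brain proteoglycans Bcan (log2 -2.25, SE 0.28), Vcan (log2 -2.01, SE 0.27) and Ncan (log2 -1.84, SE 0.28). Mitosis genes were lower for 2 of 17 (median log2 -0.43, 2 adjusted over the list alone, camera adjusted p = 0.0378, adjusted p = 0.205 with an estimated correlation). Fibroblast genes were lower for 2 of 5 (median log2 -1.02, 3 adjusted over the list alone, camera adjusted p = 0.0357, adjusted p = 0.13 with an estimated correlation). The DNA replication list was lower as a group (median log2 -0.62, 0 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.13 with an estimated correlation). Of its 14 genes limma called 0 over all genes, with 5 at an unadjusted p under 0.05 and a fry adjusted p = 0.00161. Interferon response genes were higher for 1 of 17 (median log2 0.16, 1 adjusted over the list alone, camera adjusted p = 0.00846, adjusted p = 0.0717 with an estimated correlation). Immediate early genes were higher for 1 of 14 (median log2 0.34, 2 adjusted over the list alone, camera adjusted p = 0.00093, adjusted p = 0.112 with an estimated correlation). Antigen presentation genes were higher for 3 of 12 (median log2 0.23, 3 adjusted over the list alone, camera adjusted p = 0.00452, adjusted p = 0.154 with an estimated correlation). The median of the last list turned to -0.11 after quantile normalization. The mesenchymal glioma and ribosomal protein lists did not pass, and the test gave a higher direction at medians of -0.28 and -0.12.

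By the rule for named genes the genes highest in P2 over P5 included the scavenger receptor Msr1 (34.98 ± 1.01 against 11.3 ± 1.36 FPKM, log2 1.55; chromosome 8, 39581685 to 39642673). The monocyte chemokine Ccl8 (105 ± 15.2 against 35.4 ± 0.901 FPKM, log2 1.53) and Klra2 of the Ly49 receptor family (24.9 ± 3.79 against 7.79 ± 0.718 FPKM, log2 1.56) were among them. So were the Toll-like receptor adaptor Myd88 (9.27 ± 0.821 against 3.06 ± 0.674 FPKM, log2 1.35) and the lysophosphatidic acid receptor Lpar5 (4.27 ± 0.319 against 1.081 ± 0.222 FPKM, log2 1.34). Hsd3b7 (6.48 and 8.73 FPKM in P2), Strada and Zscan26 (3.27 and 2.71 FPKM) were listed at 0 in both P5 libraries. In P1, Hsd3b7 stood at 4.65 FPKM in replicate 1 and was listed at 0 in replicate 4. Those lowest in P2 included the tubulin Tubb4a (10.2 ± 6.56 against 141 ± 10.1 FPKM, log2 -3.80; chromosome 17, 57080066 to 57087782) and neuronatin, Nnat (4.27 ± 2.75 against 60.8 ± 37.3 FPKM, log2 -3.51). Mcpt1 was at 5.797 ± 0.263 against 65.3 ± 16.1 FPKM, log2 -3.27. The prohormone-processing enzyme Cpe was at 3.37 ± 1.81 against 38.5 ± 12.4 FPKM, log2 -3.21. The beta globin Hbb-bs was at 3.101 ± 1.88 against 34.3 ± 1.95 FPKM, log2 -3.19. Cd247, the zeta chain of the T cell receptor, had the largest difference on this side and was listed at 0 in both P2 libraries and stood at 10.6 and 17.1 FPKM in P5, and Ten1 was likewise listed at 0 in P2, against 10.2 and 13.1 FPKM in P5. In all 663 genes passed, 113 higher and 550 lower in P2. The median of all genes was -0.16, and the split was 219 higher and 435 lower with upper-quartile scaling, 101 and 301 after quantile normalization, and 87 and 609 with equal totals. Without 1 library the count was 99 (P2 replicate 4), 128 (P5 replicate 1), 189 (P2 replicate 3) or 280 (P5 replicate 4).

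**Figure D3:**
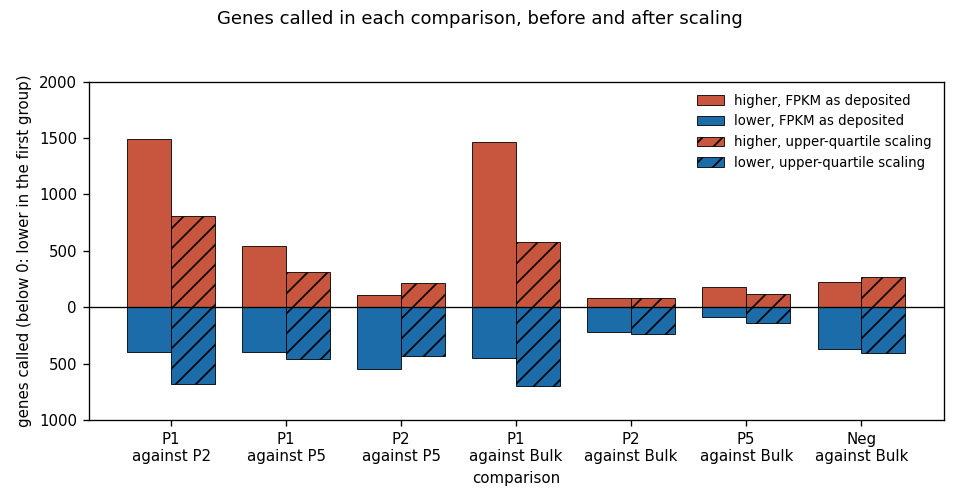
Number of genes called in 7 comparisons, drawn upwards for genes higher and downwards for genes lower in the group named first. Plain bars are the deposited FPKM and hatched bars upper-quartile scaling; P1 against P2 went from 1495 higher and 393 lower to 807 and 677.

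Against Bulk, P1 was lower in immediate early genes, again the only list to keep its call with an estimated correlation. The call of the matrix list, higher in P1, was lost there (adjusted p = 0.122). Of 14 immediate early genes 11 were lower (median log2 -1.86, 12 adjusted over the list alone, camera adjusted p = 2.81e-20, adjusted p = 0.028 with an estimated correlation). Dusp1 was at 88.4 ± 4.68 against 478 ± 17.02 FPKM, log2 -2.42 and Fos at 28.8 ± 5.37 against 139 ± 2.06 FPKM, log2 -2.24. Of 17 matrix genes 15 were higher (median log2 1.35, 15 adjusted over the list alone, camera adjusted p = 1.63e-07, adjusted p = 0.122 with an estimated correlation). Col1a2 was at 22.7 ± 2.08 against 2.48 ± 0.279 FPKM, log2 2.77 and Fn1 at 56.6 ± 15.5 against 18.1 ± 0.592 FPKM, log2 1.57. Oligodendrocyte precursor genes were higher for 6 of 12 (median log2 0.95, 7 adjusted over the list alone, camera adjusted p = 0.00276, adjusted p = 0.14 with an estimated correlation). Sox10 was at 42.3 ± 6.88 against 8.24 ± 1.76 FPKM, log2 2.23. The myelin list was lower (median log2 -0.12, 5 adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.413 with an estimated correlation), with 1 of its 13 genes higher and 2 lower. Its mean log2(FPKM + 1) was 4.57 and 4.87 in P1 and 4.59 and 5.1 in Bulk, so the libraries overlapped. The test sets the list against all other genes, and the median of all genes was 0.30 higher in P1. Mitosis genes were higher for 5 of 17 (median log2 1.02, 6 adjusted over the list alone, camera adjusted p = 0.00318, adjusted p = 0.203 with an estimated correlation), with Top2a (log2 1.37, SE 0.25) and the kinesin Kif11 (log2 1.20, SE 0.31).

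In P1, leukocyte genes were higher for 5 of 10 (median log2 0.57, 5 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.374 with an estimated correlation). Fibroblast genes were higher for 3 of 5 (median log2 2.19, 4 adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.203 with an estimated correlation). Ribosomal proteins were higher for 21 of 61, with 2 lower (median log2 0.80, 29 adjusted over the list alone, camera adjusted p = 5.83e-05, adjusted p = 0.407 with an estimated correlation). The median of the shortest class was 0.41, against 0.25 to 0.33 in the others, and the mitochondrial share was again higher in P1. Monocyte genes were lower for 3 of 9 (median log2 -0.50, 3 adjusted over the list alone, camera adjusted p = 0.00276, adjusted p = 0.122 with an estimated correlation). Lymphocyte genes were lower for 2 of 11 (median log2 -0.66, 2 adjusted over the list alone, camera adjusted p = 0.000558, adjusted p = 0.203 with an estimated correlation). Targets of p53 were lower for 5 of 12, with 1 higher (median log2 -0.67, 6 adjusted over the list alone, camera adjusted p = 0.00404, adjusted p = 0.122 with an estimated correlation). Hypoxia genes were lower for 3 of 13, with 1 higher (median log2 -0.36, 6 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.294 with an estimated correlation). Among them was the angiogenic factor Vegfa (6.84 ± 3.097 against 24.1 ± 1.498 FPKM, log2 -1.74). By the rule for named genes the largest difference on the higher side was in Slirp (47.4 and 83.3 FPKM in P1, listed at 0 in both Bulk libraries), followed by Rpl30 (75.99 ± 20.5 against 1.03 ± 0.546 FPKM, log2 5.24; chromosome 15, 34440505 to 34443640). H2-T23, a non-classical MHC class I gene, was at 67.9 ± 3.87 against 2.697 ± 0.542 FPKM, log2 4.23. The neutrophil chemokine Cxcl2 was at 1.11 ± 0.231 against 36.7 ± 2.09 FPKM, log2 -4.16. Ly6c2 was at 4.24 ± 1.07 against 60.2 ± 4.82 FPKM, log2 -3.56. Chil1 stood at 18.9 and 13.5 FPKM in Bulk, listed at 0 and at 0.325 FPKM in P1. Rpl30, H2-T23, Ly6c2 and Chil1 parted all Neg and Bulk libraries from all P1, P2 and P5 libraries. That split cannot be told from a batch. Rarres2 and Egfl8 (16.2 and 15.9 FPKM in P1) were listed at 0 in both Bulk libraries, and Plppr3 (7.95 and 12.8 FPKM in Bulk) and H2-T-ps (10.1 and 9.92 FPKM) in both P1 libraries. The median of the neuron list was 0.37 and that of mesenchymal glioma -0.11 with a mean of 0.05, both lower by a test that did not pass. In all 1917 genes passed, 1467 higher and 450 lower in P1, at a median of all genes of 0.30, and the split was 582 and 697 with upper-quartile scaling, 506 and 649 after quantile normalization and 406 and 767 with equal totals. With 1 library left out the count was 668 (Bulk replicate 2), 1035 (P1 replicate 4), 1075 (Bulk replicate 4) or 1114 (P1 replicate 1).

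P2 was lower than Bulk in myelin and astrocyte genes. Myelin genes were lower for 11 of 13 (median log2 -2.71, 11 adjusted over the list alone, camera adjusted p = 2.05e-25, adjusted p = 0.038 with an estimated correlation). Mobp was at 11.9 ± 4.02 against 509 ± 66.5 FPKM, log2 -5.33 and Mbp at 120.3 ± 35.9 against 2825 ± 93.6 FPKM, log2 -4.57. Astrocyte genes were lower for 6 of 13 (median log2 -1.29, 10 adjusted over the list alone, camera adjusted p = 2.18e-11, adjusted p = 0.038 with an estimated correlation). Gfap, the astrocyte intermediate filament, was at 2.05 ± 1.38 against 21.4 ± 4.97 FPKM, log2 -2.94. Genes of glutamate and GABA handling were lower for 4 of 11 (median log2 -0.86, 6 adjusted over the list alone, camera adjusted p = 1.11e-06, adjusted p = 0.0453 with an estimated correlation). Among them was the potassium channel Kcnj10 (log2 -1.39, SE 0.27). Endothelial genes were lower for 2 of 9 (median log2 -1.18, 5 adjusted over the list alone, camera adjusted p = 3.02e-05, adjusted p = 0.0654 with an estimated correlation), so the last test ended this call. Pecam1 was at 0.458 ± 0.00757 against 2.77 ± 0.7204 FPKM, log2 -1.36.

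In P2, leukocyte genes were higher for 1 of 10 (median log2 0.37, 2 adjusted over the list alone, camera adjusted p = 3.02e-05, adjusted p = 0.176 with an estimated correlation). Microglia genes were higher for 3 of 12, with 1 lower (median log2 0.51, 8 adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.232 with an estimated correlation). Interferon response genes were higher for 2 of 17 (median log2 0.33, 4 adjusted over the list alone, camera adjusted p = 0.000401, adjusted p = 0.053 with an estimated correlation). The leukocyte gene was Itgam, and those of interferon response were the chemokine Cxcl10 and the guanylate-binding protein Gbp2. Oligodendrocyte precursor genes were lower for 1 of 12 (median log2 -0.39, 1 adjusted over the list alone, camera adjusted p = 0.0213, adjusted p = 0.176 with an estimated correlation). Neuron genes were lower for 1 of 5 (median log2 -0.52, 1 adjusted over the list alone, camera adjusted p = 0.0228, adjusted p = 0.176 with an estimated correlation). Hypoxia genes were lower for 2 of 13 (median log2 -0.33, 3 adjusted over the list alone, camera adjusted p = 0.0228, adjusted p = 0.271 with an estimated correlation). Ribosomal proteins were higher for 1 of 61 (median log2 0.17, 1 adjusted over the list alone, camera adjusted p = 0.0228, adjusted p = 0.615 with an estimated correlation). The rule for named genes gave the alarmin Il33 (0.505 ± 0.282 against 31.3 ± 2.68 FPKM, log2 -4.43) and the metallothionein Mt2 (6.73 ± 0.228 against 147 ± 14.4 FPKM, log2 -4.25; chromosome 8, 94172664 to 94173568) on the lower side. The protease Klk6 was lower too (0.886 ± 0.371 against 32.8 ± 6.11 FPKM, log2 -4.16). On the higher side it gave Rpl30 (53.8 ± 8.01 against 1.03 ± 0.546 FPKM, log2 4.77) and H2-T23 (68.9 ± 7.22 against 2.697 ± 0.542 FPKM, log2 4.25). Tmem14c (31.1 ± 4.62 against 1.14 ± 0.573 FPKM, log2 3.92) and the DNA ligase Lig1 (18.4 ± 0.269 against 2.46 ± 1.297 FPKM, log2 2.54) were higher as well, and Strada was listed at 0 in both Bulk libraries. Rpl30, H2-T23, Tmem14c and Gbp2 parted all Neg and Bulk libraries from all P1, P2 and P5 libraries, a split that cannot be told from a batch. Of the lists that did not pass, lymphocytes (median 0.19, mean -0.01, higher by the test), secreted synaptogenic factors (0.06 and -0.18, lower), mesenchymal glioma (0.01 and -0.02, lower) and matrix (-0.14 and 0.02, higher) differed in sign. In all 303 genes passed, 85 higher and 218 lower in P2. Without 1 library the count was 102 (P2 replicate 4), 105 (Bulk replicate 4), 137 (P2 replicate 3) or 138 (Bulk replicate 2).

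P5 carried more oligodendrocyte precursor transcripts than Bulk, in the only list here to keep its call with an estimated correlation. The lymphocyte list, higher in P5, lost its call there (adjusted p = 0.131). Precursor genes were higher for 7 of 12 (median log2 1.51, 12 adjusted over the list alone, camera adjusted p = 6.04e-11, adjusted p = 0.0385 with an estimated correlation). The calcium channel subunit gene Cacng4 was at 10.1 ± 1.103 against 0.859 ± 0.229 FPKM, log2 2.58. Olig2 was at 22.2 ± 1.88 against 5.41 ± 1.65 FPKM, log2 1.88 and Vcan at 21.04 ± 1.11 against 5.19 ± 1.45 FPKM, log2 1.85. Of 11 lymphocyte genes 5 were higher (median log2 1.72, 7 adjusted over the list alone, camera adjusted p = 3.72e-06, adjusted p = 0.131 with an estimated correlation). Gzmb was at 26.4 ± 1.805 against 2.91 ± 0.218 FPKM, log2 2.81 and Cd4, the helper T cell co-receptor, at 25.98 ± 1.28 against 6.22 ± 0.182 FPKM, log2 1.90. Myelin genes were lower for 4 of 13 (median log2 -0.57, 4 adjusted over the list alone, camera adjusted p = 5.28e-06, adjusted p = 0.154 with an estimated correlation). Mobp was at 109 ± 26.9 against 509 ± 66.5 FPKM, log2 -2.23.

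In P5, mitosis genes were higher for 1 of 17 (median log2 0.87, 6 adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.131 with an estimated correlation). The gene called was Tpx2 (log2 1.63, SE 0.35). DNA replication genes were higher for 1 of 14 (median log2 0.79, 6 adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.0745 with an estimated correlation). Here it was Mcm2 (log2 1.54, SE 0.32). Matrix genes were higher for 3 of 17 (median log2 0.77, 10 adjusted over the list alone, camera adjusted p = 0.000267, adjusted p = 0.131 with an estimated correlation). Microglia genes were lower for 2 of 12 (median log2 -0.32, 2 adjusted over the list alone, camera adjusted p = 0.000237, adjusted p = 0.131 with an estimated correlation). Monocyte genes were lower for 1 of 9 (median log2 -0.78, 2 adjusted over the list alone, camera adjusted p = 0.000237, adjusted p = 0.0745 with an estimated correlation). Endothelial genes were lower for 1 of 9 (median log2 -0.27, 1 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.131 with an estimated correlation). The astrocyte and immediate early lists were lower as groups, though limma called 0 of their 13 and 14 genes over all genes. The astrocyte list, with 3 at an unadjusted p under 0.05, had a median log2 -0.26, 1 adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.225 with an estimated correlation. The immediate early list, with 7 at an unadjusted p under 0.05, had a median log2 -0.22, 3 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.228 with an estimated correlation. By fry the lists gave adjusted p = 0.297 and adjusted p = 0.222. By the rule for named genes the genes highest over Bulk were Rpl30 (57.1 ± 18.9 against 1.03 ± 0.546 FPKM, log2 4.83) and H2-T23 (66.1 ± 7.21 against 2.697 ± 0.542 FPKM, log2 4.19). Tmem14c was at 24.2 ± 7.82 against 1.14 ± 0.573 FPKM, log2 3.55 and Lig1 at 34.5 ± 4.72 against 2.46 ± 1.297 FPKM, log2 3.41. Granzyme A, Gzma, was at 9.29 ± 1.96 against 0.305 ± 0.226 FPKM, log2 2.98. Those lowest included cathepsin E, Ctse (0.932 ± 0.282 against 30.1 ± 3.73 FPKM, log2 -4.01; chromosome 1, 131638306 to 131675505), and Apoc2 (5.84 ± 5.14 against 84.8 ± 5.29 FPKM, log2 -3.89). The chaperone Hspb1 was at 7.33 ± 0.896 against 74.8 ± 8.88 FPKM, log2 -3.18. The crystallin Crybb1 was at 8.67 ± 1.35 against 60.5 ± 2.78 FPKM, log2 -2.67. Chil1 was listed at 0 and at 0.149 FPKM in P5. Of the genes named here, Rpl30, H2-T23, Tmem14c, Ctse, Hspb1 and Chil1 parted all Neg and Bulk libraries from all P1, P2 and P5 libraries. That split cannot be told from a batch, so they do not mark P5 alone. The mesenchymal glioma (median 0.14) and p53 target (0.09) lists did not pass, and the test gave a lower direction. In all 272 genes passed, 184 higher and 88 lower in P5, at a median of all genes of 0.19, and the split was 121 and 134 with upper-quartile scaling, 136 and 129 after quantile normalization, and 176 and 59 with equal totals, which kept the main split. With 1 library left out the count was 43 (Bulk replicate 2), 52 (Bulk replicate 4), 53 (P5 replicate 1), 72 (P5 replicate 4), 169 (P2 replicate 4) or 171 (P2 replicate 3).

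**Figure D4:**
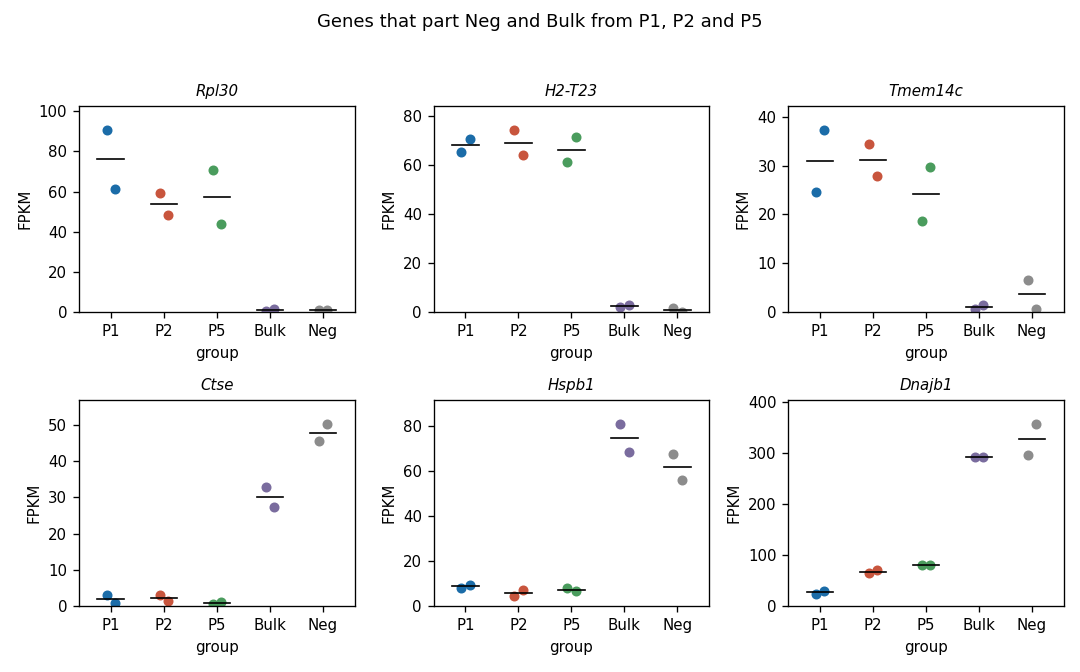
FPKM of 6 genes in each of the 10 libraries, by group, chosen after their values were seen. Points are libraries and bars the mean of the 2 libraries; Rpl30 lay between 0.647 and 1.42 FPKM in the 4 Neg and Bulk libraries and between 43.7 and 90.5 FPKM in the other 6.

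Neg was higher than Bulk in lymphocyte genes and lower in myelin and astrocyte genes, though the myelin list lost its call with an estimated correlation (adjusted p = 0.0545). Of 11 lymphocyte genes 10 were higher in Neg (median log2 2.23, 11 adjusted over the list alone, camera adjusted p = 1.3e-18, adjusted p = 0.0307 with an estimated correlation). Cd3e was at 289 ± 5.46 against 32.7 ± 0.305 FPKM, log2 3.11, Nkg7 at 196 ± 59.9 against 30.01 ± 2.84 FPKM, log2 2.64 and the inhibitory T cell receptor Ctla4 at 107 ± 5.28 against 10.9 ± 0.656 FPKM, log2 3.17. Myelin genes were lower for 10 of 13 (median log2 -2.53, 12 adjusted over the list alone, camera adjusted p = 8.16e-16, adjusted p = 0.0545 with an estimated correlation). Mbp was at 310.1 ± 33.9 against 2825 ± 93.6 FPKM, log2 -3.19. Astrocyte genes were lower for 9 of 13 (median log2 -1.29, 11 adjusted over the list alone, camera adjusted p = 8.53e-11, adjusted p = 0.0307 with an estimated correlation). Ndrg2 was at 4.28 ± 1.93 against 36.4 ± 3.44 FPKM, log2 -2.87. Globin transcripts of red cells were higher in Neg and spread widely: Hba-a1 was at 48.4 ± 28.1 against 3.58 ± 2.44 FPKM, log2 3.41, and Hbb-bs at 153 ± 106 against 12.7 ± 6.38 FPKM, log2 3.38.

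In Neg, genes of glutamate and GABA handling were lower for 5 of 11 (median log2 -1.18, 10 adjusted over the list alone, camera adjusted p = 4.68e-08, adjusted p = 0.0307 with an estimated correlation). Matrix genes were lower for 6 of 17 (median log2 -0.94, 13 adjusted over the list alone, camera adjusted p = 1.75e-05, adjusted p = 0.0839 with an estimated correlation). Oligodendrocyte precursor genes were lower for 2 of 12 (median log2 -0.60, 4 adjusted over the list alone, camera adjusted p = 0.00113, adjusted p = 0.0839 with an estimated correlation). Endothelial genes were lower for 2 of 9 (median log2 -1.03, 7 adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.0839 with an estimated correlation). Fibroblast genes were lower for 2 of 5 (median log2 -1.06, 4 adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.0693 with an estimated correlation). Secreted synaptogenic factors were lower for 3 of 8 (median log2 -1, 5 adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.161 with an estimated correlation). Interferon response genes were lower for 2 of 17 (median log2 -0.34, 3 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.0839 with an estimated correlation). The mitosis list was higher as a group (median log2 0.36, 0 adjusted over the list alone, camera adjusted p = 0.0445, adjusted p = 0.272 with an estimated correlation). Of its 17 genes limma called 0 over all genes, with 2 at an unadjusted p under 0.05 and a fry adjusted p = 0.119. The rule for named genes also gave the natural killer cell receptor Klrd1 (37.1 ± 14.6 against 3.27 ± 2.75 FPKM, log2 3.27; chromosome 6, 129591782 to 129598775) and the T cell chemokine Xcl1 (59.4 ± 14.8 against 7.04 ± 6.64 FPKM, log2 3.19) on the higher side. On the lower side it gave prostaglandin D2 synthase, Ptgds (10.4 ± 2.46 against 163 ± 5.99 FPKM, log2 -3.86), and Pex5l (0.9504 ± 0.187 against 19.2 ± 0.802 FPKM, log2 -3.37). Apod was at 18.3 ± 7.21 against 190.1 ± 16.1 FPKM, log2 -3.36 and S100a16 at 0.8699 ± 0.752 against 17.2 ± 0.569 FPKM, log2 -3.34. Cryab was at 27.1 ± 2.91 against 276 ± 9.68 FPKM, log2 -3.31. In all 589 genes passed, 223 higher and 366 lower in Neg, and the split was 267 and 408 with upper-quartile scaling, 282 and 317 after quantile normalization and 293 and 311 with equal totals. Without 1 library the count was 228 (Bulk replicate 4), 248 (Bulk replicate 2) or 314 (Neg replicate 1).

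Set against the mean of P1, P2 and P5, Neg was higher in lymphocyte genes and lower in matrix genes. All 11 lymphocyte genes were higher (median log2 2.38, 11 adjusted over the list alone, camera adjusted p = 2.87e-16, adjusted p = 0.0462 with an estimated correlation). Cd8a, the cytotoxic T cell co-receptor, was at 48.9 ± 4.53 FPKM in Neg, 1.801 ± 1.92 in P1, 3.48 ± 2.33 in P2 and 9.01 ± 2.14 in P5 (log2 3.42, SE 0.40). Jchain, the joining chain of secreted antibodies, was at 101 ± 2.69 FPKM in Neg, 1.88 ± 0.156 in P1, 3.95 ± 0.359 in P2 and 8.16 ± 2.25 in P5 (log2 4.34, SE 0.21; chromosome 5, 88519809 to 88527891). The B cell coactivator Pou2af1 was at 43.7 ± 6.25 FPKM in Neg (log2 3.46, SE 0.28). Matrix genes were lower for 15 of 17 (median log2 -1.68, 17 adjusted over the list alone, camera adjusted p = 1.55e-08, adjusted p = 0.0462 with an estimated correlation). The matrix protein periostin, Postn, was at 0.8098 ± 0.105 FPKM in Neg, 79.97 ± 2.97 in P1, 12.1 ± 2.88 in P2 and 22.3 ± 5.36 in P5.

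In Neg, oligodendrocyte precursor genes were lower for 10 of 12 (median log2 -1.36, 11 adjusted over the list alone, camera adjusted p = 5.65e-06, adjusted p = 0.0462 with an estimated correlation). Astrocyte genes were lower for 9 of 13 (median log2 -1.16, 11 adjusted over the list alone, camera adjusted p = 3.37e-05, adjusted p = 0.0462 with an estimated correlation). Genes of glutamate and GABA handling were lower for 9 of 11 (median log2 -1.16, 11 adjusted over the list alone, camera adjusted p = 3.54e-05, adjusted p = 0.0462 with an estimated correlation). Fibroblast genes were lower for 4 of 5 (median log2 -2.18, 5 adjusted over the list alone, camera adjusted p = 0.000535, adjusted p = 0.0462 with an estimated correlation). Interferon response genes were lower for 10 of 17 (median log2 -0.78, 11 adjusted over the list alone, camera adjusted p = 0.000466, adjusted p = 0.0462 with an estimated correlation). Myelin genes were lower for 8 of 13 (median log2 -0.92, 11 adjusted over the list alone, camera adjusted p = 0.000216, adjusted p = 0.212 with an estimated correlation). The mean log2(FPKM + 1) of the myelin list was 2.41 and 2.64 in the Neg libraries, 4.57 and 4.87 in P1 and 4.27 and 4.2 in P5, but 2.19 and 2 in P2, so Neg lay below P1 and P5 and above P2. Leukocyte genes were lower for 6 of 10 (median log2 -0.73, 8 adjusted over the list alone, camera adjusted p = 0.00847, adjusted p = 0.35 with an estimated correlation). Ribosomal proteins were lower for 23 of 61, with 1 higher (median log2 -0.61, 34 adjusted over the list alone, camera adjusted p = 0.00025, adjusted p = 0.516 with an estimated correlation). Synapse genes were lower for 6 of 14 (median log2 -0.64, 7 adjusted over the list alone, camera adjusted p = 0.0321, adjusted p = 0.143 with an estimated correlation). By that mean Neg replicate 3, at 1.33, lay above P2 replicate 4, at 1.32, so Neg was not apart from P2. Secreted synaptogenic factors were lower for 6 of 8, with 1 higher (median log2 -1.54, 7 adjusted over the list alone, camera adjusted p = 0.00303, adjusted p = 0.189 with an estimated correlation). Immediate early genes were higher for 7 of 14 (median log2 0.44, 7 adjusted over the list alone, camera adjusted p = 1.72e-05, adjusted p = 0.0688 with an estimated correlation), with Ier2 (log2 1.16, SE 0.19) and Jun (log2 0.77, SE 0.14). The mean of this list was 6.07 and 6.01 in the Neg libraries and 4.71 and 4.47 in P1, but 6.29 and 6.32 in P2 and 6.07 and 6.06 in P5, so Neg lay above P1 alone. The rule for named genes added Ctse (log2 4.23, SE 0.29), Klrd1 (log2 3.62, SE 0.41), H2-T23 (log2 -5.35, SE 0.31), Rpl30 (log2 -4.82, SE 0.25), H2-DMb1 (log2 -3.58, SE 0.75) and S100a16 (log2 -3.51, SE 0.28). H2-T23 was listed at 0 in Neg replicate 3 and H2-DMb1 in Neg replicate 1. Ctse, H2-T23, Rpl30 and H2-DMb1 parted all Neg and Bulk libraries from the others, so they do not mark Neg alone. The monocyte (median -0.18) and hypoxia (-0.11) lists did not pass, and the test gave a higher direction. Of all genes 2539 passed, and in 1844 of them the Neg libraries lay wholly above or wholly below those of P1, P2 and P5. They split into 566 higher and 1973 lower in Neg, at a median of all genes of -0.25, and the split was 820 and 1179 with upper-quartile scaling, 832 and 897 after quantile normalization and 889 and 1035 with equal totals. Leaving out Neg replicate 1 gave 1128 genes.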

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

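The scaling to equal totals, the wider transcript match, the keeping of genes without OK status, the adjustment over 8 comparisons and the fit of the P1, P2 and P5 libraries alone were chosen after the data were seen. Of 102 list calls among 200 list tests, 100 kept 1 direction under all settings and 23 also stayed past the threshold in each. Of 556 gene calls, 200 stayed past it in each. With an estimated correlation, which allows for genes that move together, 23 of the 102 list calls held, and by fry 90 did. Why calls were lost was not tested. Leaving out 1 library gave 96 to 106 list calls.

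Gene counts moved by over 1.5 times as follows, and the cause was not tested unless given. The replicate block, which rests on shared numbers alone (r = 0.005 across genes for the differences between replicates 1 and 4 of P1 and P5) and leaves 2 residual degrees of freedom, gave 1070 for P1 against P2, 559 for P1 against P5, 195 for P2 against P5, 1011 for any difference among these, 251 for P1 against Bulk, 62 for P2 against Bulk, 1 for P5 against Bulk, 17 for Neg against Bulk and 1523 for Neg against the mean. Quantile normalization gave 580 for P1 against P5, 402 for P2 against P5 and 1155 for P1 against Bulk, and equal totals gave 1173 for the last. A fit of only the groups compared, with fewer samples, gave 451 for P1 against P5, 140 for P5 against Bulk and 124 for Neg against Bulk. Without a filter 388 were called for P2 against P5 and 153 for P5 against Bulk, and with a mean of at least 5 FPKM 437 for P2 against P5. Library weights gave 1066 for P2 against P5 and 525 for P2 against Bulk. A pseudocount of 0.1 gave 139 for P5 against Bulk. Adjustment over the 8 comparisons together gave 478 for P2 against Bulk and 545 for P5 against Bulk.

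After quantile normalization 5 results reversed: antigen presentation in P1 against P5 (adjusted p = 0.287) and P2 against P5 (adjusted p = 0.689), Cd74 in P1 against P2 (log2 -0.16), and B2m in P1 against P5 (log2 0) and in Neg against the mean (log2 0.03). The cause was not tested.

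With 1 library left out, so that a lone library is assumed to vary like the other groups, counts ran from 672 to 2066 for P1 against P2, 324 to 1136 for P1 against P5, 99 to 739 for P2 against P5, 899 to 2208 for any difference, 668 to 2194 for P1 against Bulk, 102 to 345 for P2 against Bulk, 43 to 305 for P5 against Bulk, 228 to 651 for Neg against Bulk and 1128 to 2423 for Neg against the mean. Depth in fragments is unknown, so what depth limits could not be stated beyond the relative depth of 0.59 to 1.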

Other observations

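Of the tests in this part, those on genes with shared sequence, over all 23 genes, and on the second T cell list were set before their results were seen, and the others were chosen after. Heat shock genes, a list chosen after its values were seen, were lower than in Bulk for 11 of 12 genes in P1 (median log2 -2.44), 10 of 12 in P2 (-1.32) and 9 of 12 in P5 (-1.28). In Neg against Bulk limma called 0 of the 12 (median -0.05). Transcripts left without a gene name carried 9.1% and 9.8% of the FPKM in Neg and 4.8% to 5.6% elsewhere. One of them, at chromosome 6, 70718902 to 70726754, in the immunoglobulin kappa locus, stood at 2301 and 3304 FPKM in Neg, 370.4 and 521 FPKM in Bulk and 56.7 to 266 FPKM in P1, P2 and P5. Another, at chromosome 12, 113258716 to 113429513, in the immunoglobulin heavy chain locus, stood at 937 and 1382 FPKM in Neg and at most 195.8 FPKM elsewhere. Of 18 tested genes of a second T cell list, 15 were higher in Neg than in Bulk (median log2 2.27).

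The ratio of coverage to FPKM lay within 1% of its median for 96.8% of transcripts in P5 replicate 1, and for 22.6% to 27.5% in the other 9 libraries. There were 28 tested genes listed at 0 in a library and at 20 FPKM or more in another, so a single 0 is not read as absence.

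A group of 23 genes, Rpl30 and H2-T23 among them, lay apart by over 1 on the log2 scale between all Neg and Bulk libraries and all others. A haplotype of the major histocompatibility region as the whole cause is argued against by the 17 genes outside it, although 6 of the 100 tested genes of the region were among them (Fisher exact p = 5.55e-08). Of the 23 genes 6 are heat shock genes, all higher in Neg and Bulk: Hspa1a and Hspa1b in the region and Dnajb1, Dnaja1, Hspb1 and Bag3 outside it. Without the heat shock list 4 of 98 genes of the region remained, all H2 genes lower in Neg and Bulk (Fisher exact p = 1.53e-05), against 13 genes outside it. For reads shared with near-identical copies the bound set was met. Of these genes 47.8% shared words with other genes, against 8.8% of all genes (Fisher exact p = 1.13e-06), but the other 12 shared less than 10%. Shared sequence is the same for every library, so it could part the groups only through something else that differed between them. The test therefore names no cause. Of the 11 genes that shared words 4 are heat shock genes, and without that list the share was 41.2% against 8.7% (Fisher exact p = 0.000334). For a difference in preparation or read processing, the bound set for the test was met, as Neg with P2 gave 53 such genes against 23, which was first read as excluding it. That bound was wrong, since the 53 include myelin and astrocyte genes such as Mbp, Plp1 and S100b, all lower in both groups, and say nothing about a batch. The split follows whole groups, so batch and group cannot be told apart.

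Immediate early genes were lower in P1 than in P2, P5 and Bulk. The median in P1 against P2 was -1.75 in the deposited values, and no scaling tried brought it closer to 0. The scalings lower P1 in the median of all genes, from 0.26 to -0.002 (upper-quartile), -0.041 (quantile) and -0.103 (equal totals). They could hardly have raised the list, and show only that the higher totals of P1 do not account for it. Fewer myeloid cells as a whole are argued against, as the median of the leukocyte list was no lower than -0.27 under any scaling tried. Fewer monocytes in P1 stay open and were not tested, since the monocyte list was lower for 4 of 9 genes in P1 against P2 (median log2 -0.29, camera adjusted p = 0.000345), though it lost its call with an estimated correlation (adjusted p = 0.0633). Shorter or gentler handling of P1 could also lower heat shock genes, whose median was -0.89 in P1 against P2, between the bounds set, -1.08 in P1 against P5 and -2.44 in P1 against Bulk. P2 and P5 were also lower than Bulk in heat shock genes (-1.32 and -1.28), while their immediate early medians against Bulk were 0.08 and -0.22. Those comparisons cross the split that cannot be told from a batch, and 6 heat shock genes are among its 23 genes. They thus cannot say whether the lists move together. Of 12 heat shock genes 7 were lower in P1 than in P2, and 7 were lower in P1 than in P5, with 0 higher in either. Handling is not recorded and follows the groups, so it cannot be told apart from a difference between the populations, which was not tested.

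Of 11 lymphocyte genes 9 were higher in P5 than in P1, and the list lost its call with an estimated correlation (adjusted p = 0.0814). The median in P1 against P5 was -1.95 in the deposited values, and no scaling tried brought it closer to 0. The scalings lower P1 in the median of all genes here too, from 0.11 to -0.023 (upper-quartile), 0.035 (quantile) and -0.368 (equal totals). They show only that the higher totals of P1 do not account for the difference. A lower share of myeloid cells in P5 that raises every other cell type alike is argued against, as the lymphocyte and astrocyte medians lay 2.64 apart. A lower share as such stays open, since 6 of 10 leukocyte and 3 of 12 microglia genes were lower in P5 (medians 0.84 and 0.64 in P1 against P5). The precursor list had a median of -0.73 with 0 of 12 genes called, and all 3 lists lost their calls with an estimated correlation (adjusted p = 0.199, 0.199 and 0.184). T cells or their RNA in P5 may contribute, since 61.1% of the second T cell list (11 of 18 genes) was higher in P5, with 1 gene, Ccl5, lower. That share is short of the bound set for this explanation, so it stays open. The gates of each population are not in the labels, and a biological difference between populations was not tested.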
